A study of Homo sapiens with 12 samples.

How the data were processed

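Gene expression was measured in human embryonic kidney (HEK) cell clones that stably express either the G protein-coupled receptor kinase GRK2 or its kinase-deficient K220R form. The 12 arrays fall into 6 groups of 2, made of 2 genotypes in 3 growth conditions: clones kept in culture, clones grown during 4 weeks in mice of the NOD.Scid strain (immunodeficient, aged 3 months), and clones returned to culture after expansion in mice. Group and replicate number were taken from the sample titles. No array of HEK cells without a GRK2 construct was used here.

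Per the labels' protocols, total RNA was made into biotinylated cRNA and hybridised to 1-colour Affymetrix arrays. Per the submitters' processing notes the authors used GCOS, whose version was not stated. The deposited values are one linear signal intensity per probe set and array. The signal algorithm, the scaling target and any detection calls are not given in the sources used here. After 2% of probe sets were trimmed at each end, the mean signal was between 200.02 and 200.025 on all 12 arrays, so each array had been scaled to a common trimmed mean. No further normalization between arrays was seen in the values, and the deposited scaling was kept. Scanner files and scan dates were not analysed here, so no technical batch could be tested.

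The table held 54675 probe sets, of which 62 control probe sets were left out. By the platform annotation used here, 41091 of the remaining 54613 probe sets had 1 gene symbol, 1801 had several and 11721 had none listed. No symbol (0) needed an update through its Entrez identifier. Probe sets with several or no symbols stayed in the tests and were given no gene name. For statements on genes, each gene was represented by 1 probe set, the one with the highest mean log2 value over all arrays among those assigned to that gene alone. This gave 19775 genes. Other probe sets of a gene are mentioned in some cases where they disagreed, so silence on them does not mean that they moved together. Probe sets that can bind several near-identical family members, as for the MAGE and PRAME families, do not separate those members.

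Signals were transformed to log2(signal + 16). All log2 differences are on this scale, which understates the change of dim probe sets. A probe set was tested when its signal exceeded the array's own median (percentile 50) on at least 2 arrays. That left 31908 probe sets and 13946 genes. One limma model with a mean per group was fitted over all 12 arrays (lmFit and eBayes with an intensity trend, residual degrees of freedom 6, median prior degrees of freedom 5.55). All tests were two-sided, with Benjamini-Hochberg adjustment over all probe sets tested within a comparison and a threshold of 0.05. Values written with ± are log2 differences and their standard errors, unless an SD is named.

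The 10 comparisons were K220R against GRK2 as the mean of the 3 growth conditions and within each condition, the 3 pairs of growth conditions averaged over both genotypes, and the 3 differences of the genotype effect between conditions (interactions). The groups, comparisons, tests, gene lists, naming rule and first set of other settings were fixed before the data were examined. The labels do not say whether replicates are separate clones, cultures or mice. The p-values therefore measure only the spread between these samples, which may be technical, and a property of a single clone cannot be separated from an effect of the genotype.

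Genes were named by a fixed rule. GRK2 and the other GPCR kinases and arrestins were always taken. In each comparison, genes past the threshold whose direction was the same on every array of one side against the other (not asked of interactions) were ranked by size. The first 10 rises and 10 falls were taken in the mean genotype effect and in both comparisons with cultured cells, and 6 and 6 elsewhere. Up to 4 members with the smallest p were taken from each list that was called or had at least 3 called members, and the 3 members of highest level from lists of other cell types. Names were left out for length.

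There were 28 gene lists: GPCR kinases and arrestins, RGS proteins, ERK response genes, the RAF MEK ERK cascade, cAMP CREB response genes, PPAR gamma targets and lipid droplets, fatty acid synthesis, cholesterol synthesis, hypoxia response, glycolysis, cell cycle, interferon response, NF-kappaB and inflammatory genes, unfolded protein and integrated stress response, heat shock response, YAP and TGF-beta targets, Wnt targets, respiratory chain, neuronal genes of HEK cells, renal development genes, and cell adhesion and junction genes. The other 7 hold markers of other cell types, namely fibroblast and matrix, endothelium, leukocyte and macrophage, red cell, adipocyte, skeletal muscle and keratinocyte. For each list the members past the threshold were counted over all genes tested and adjusted over the list alone. Only members that passed the filter were tested, so a dim member could enter a list through the groups where it was high. Each list was compared with all other genes by camera with a preset correlation of 0.01, adjusted over the 28 lists. A list was called at an adjusted p under 0.05, and the same test was repeated with an estimated correlation.

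Correlations of effects across genes were computed for 5 pairs of comparisons that share no arrays. Overlaps of calls were set beside the number given by independent lists (the product of both counts divided by the genes tested).

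The scripts were tested on simulated data with 200 of 31908 probe sets changed. In the mean genotype effect, 77% of changes of 1.5-fold, 96% of 2-fold and 100% of 4-fold were recovered. Within cultured cells the shares were 39.5%, 74% and 98%, and for mouse-expanded against cultured cells 61%, 89.5% and 100%. For the interaction of mouse-expanded and cultured cells they were 1%, 50% and 93%. False calls numbered 0 to 11 per simulation. In each of the 3 comparisons in which lists were simulated, all 4 shifted lists and 0 others were called. The simulated noise was independent between genes and equal in all groups. It therefore cannot show false calls of lists whose genes vary together. Far fewer probe sets were changed than were called in the data, so the recovered shares may differ there. The precision of all values is limited by the number of arrays, 2 per group.

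The other settings fixed in advance were a pseudocount of 1 or 64, quantile normalization, no filter, a filter at percentile 75 or on the mean level, no intensity trend, 1 probe set per gene, an added 2-fold threshold, fits on only the arrays compared, the replicate number as a block, and leaving out each array in turn. Later additions, chosen after seeing the data, were the mean genotype effect without mouse-expanded arrays, growth comparisons in K220R clones only, and tests of protein-coding genes only. The analysis used R 4.3.3, limma 3.58.1 and data.table (version 1.17.8), and figures were drawn with Python 3.11.15 and matplotlib 3.10.9.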

Results

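The series profiled gene expression in HEK cells, a human embryonic kidney line, to separate effects of GRK2 that need its kinase activity from those that do not. GRK2 phosphorylates activated G protein-coupled receptors, and the K220R form keeps the protein but lacks kinase activity. Clones with either form were profiled in culture, after expansion in mice and again in culture after that expansion, with 2 arrays for each of the 6 groups. The median signal per array ranged from 28.3 to 48.3. The correlation of log2 signals between the replicates of a group was between 0.978 and 0.988, lowest for re-cultured GRK2. The signal ratio of 3' to 5' probe sets ranged from 0.981 to 1.15 for GAPDH and from 1.25 to 1.41 for ACTB. The number of arrays limits the precision of every comparison.

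GRK2 signal, read by its brightest probe set, was 1219 ± 112 (SD, n = 2) in cultured GRK2 clones and 1320 ± 46.2 in cultured K220R clones. After expansion in mice it was 1877 ± 217 in GRK2 and 6370 ± 725 in K220R clones, and after re-culture 6044 ± 961 in GRK2 and 3404 ± 367 in K220R clones. K220R clones thus had more of this signal in the mouse-expanded state (1.75 ± 0.13, adjusted p = 4.0e-06) and less in the re-cultured state (-0.82 ± 0.13, adjusted p = 0.0017). In culture the difference was 0.12 ± 0.13 (adjusted p = 0.687). The genotype effect differed between mouse-expanded and cultured cells by 1.64 (adjusted p = 2.7e-04) and between mouse-expanded and re-cultured cells by 2.58 (adjusted p = 1.4e-05). Between re-cultured and cultured cells it differed by -0.94 (adjusted p = 0.0379), a call that ended when any 1 array of those 8 except replicate 2 of re-cultured GRK2 was left out and, over all alternatives, had adjusted p values from 0.00752 to 0.142. The mean genotype effect on GRK2 was 0.35 ± 0.07 (adjusted p = 0.00394) and turned to -0.35 without the mouse-expanded arrays (adjusted p = 0.0183), so GRK2 has no single direction. Compared with culture, GRK2 signal rose in mouse-expanded cells (1.43 ± 0.09, adjusted p = 2.0e-07) and in re-cultured cells (1.82 ± 0.09, adjusted p = 1.3e-07). The other GRK2 probe sets, one with a middle level and one near background, passed the test in none of the 10 comparisons. For the one of middle level the K220R difference in mouse-expanded cells was 0.09 ± 0.24. The labels do not tie the probe sets to the transfected or the endogenous transcript.

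**Figure D1:**
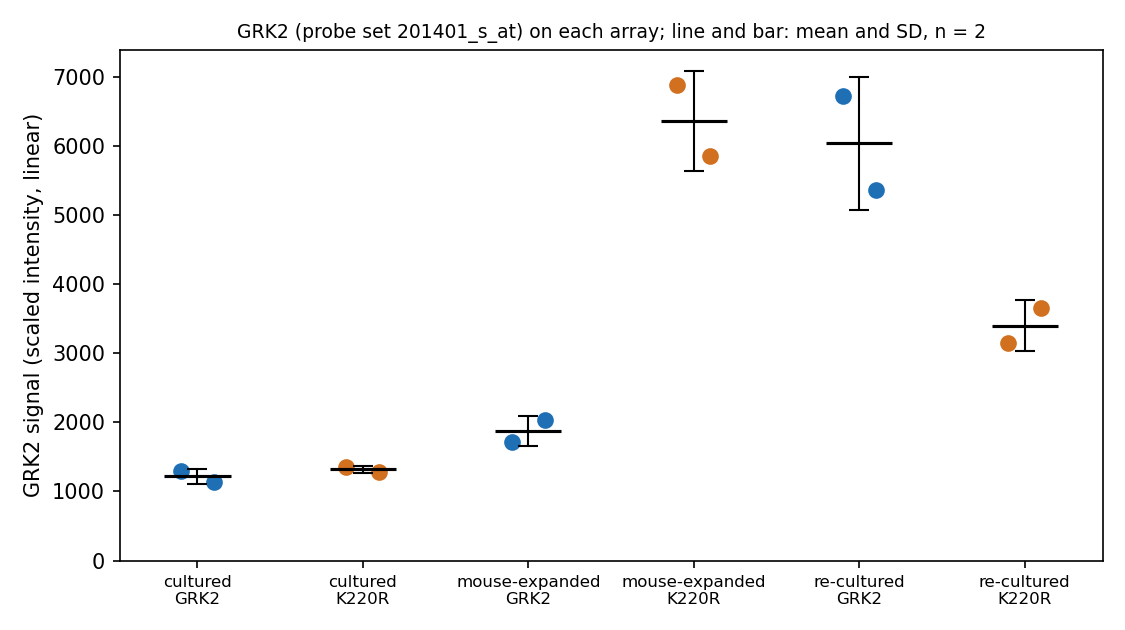
Signal of the brightest GRK2 probe set (linear units, y axis) in each of the 6 groups (x axis); points are single arrays, and bars with error lines give the mean and SD of 2 arrays, blue for GRK2 and orange for K220R clones. Cultured groups lie near 1219 and 1320, while mouse-expanded K220R and re-cultured GRK2 clones reach 6370 and 6044.

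Among the other receptor kinases and arrestins, GRK5 rose in the mean of K220R clones (0.27, adjusted p = 0.0051). Without the mouse-expanded arrays its difference was 0.06, the highest of its adjusted p values, which ranged from 0.0023 to 0.65. GRK3 and the representative GRK6 probe set did not pass (0.18 and -0.12), though 2 of the other 3 GRK6 probe sets were lower. In mouse-expanded cells the representative GRK6 probe set was higher in K220R clones (0.43, adjusted p = 0.013) while 2 of the other 3 were lower, so GRK6 is given no direction there. That call also ended without replicate 1 of mouse-expanded GRK2 (adjusted p = 0.115) or replicate 1 of mouse-expanded K220R (0.0857), in a range from 0.0120 to 0.115. GRK4 fell by 0.48 and ARRB1 (beta-arrestin 1) fell by 0.23, but both calls were lost after quantile normalization, without the filter and without the mouse-expanded arrays, with highest adjusted p values over the alternatives of 0.093 and 0.28. The GRK4 call was also lost without replicate 2 of mouse-expanded GRK2 (adjusted p = 0.080), replicate 1 of mouse-expanded K220R (0.078), replicate 2 of cultured GRK2 (0.084), replicate 2 of cultured K220R (0.083), replicate 2 of re-cultured GRK2 (0.051) or replicate 1 of re-cultured K220R (0.067). The ARRB1 call was lost without any 1 array other than replicate 2 of re-cultured GRK2 or replicate 1 of re-cultured K220R, with adjusted p values from 0.056 to 0.094. Of the 6 measured members of this list, 2 rose, 2 fell and 2 did not pass, with the same counts adjusted over the list alone (camera adjusted p = 0.960). Other probe sets of GRK5 and ARRB1 did not all share these directions. An ARRB1 probe set of nearly equal mean signal (132 against 134) was lower in cultured K220R clones but not in re-cultured ones (114.2 and 94.3 against 66.9 and 94.5). The second brightest GRK5 probe set was lower in cultured K220R clones (37.6 and 50.1 against 69.5 and 82.4).

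The first principal component held 42.0% of the variance of tested probe sets and set the 4 mouse-expanded arrays apart from the other 8. The second and the third held 18.9% and 12.5%. The mouse-expanded GRK2 arrays also had the highest median signals, 47.8 and 48.3, against at most 35.2 on the other arrays.

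**Figure D2:**
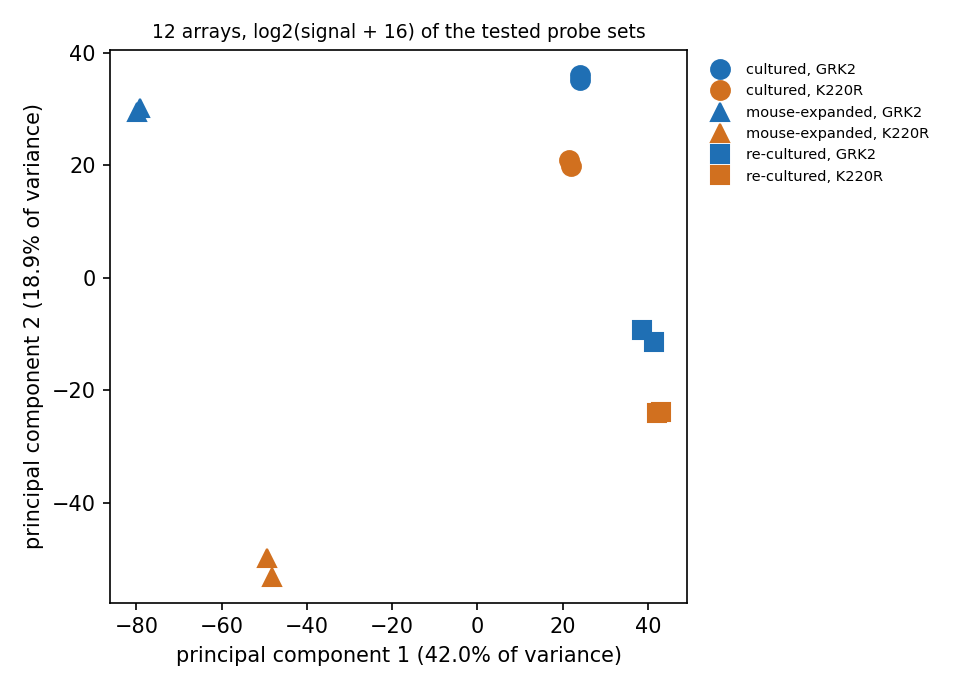
The 12 arrays on the first and second principal components of log2(signal + 16) over the tested probe sets, with the percent of variance on each axis (42.0 and 18.9) and colour and marker giving genotype and growth condition. The 4 mouse-expanded arrays lie apart from the other 8 on the first component.

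The comparison of K220R with GRK2 clones, averaged over growth conditions, asked which genes differ on average between clones expressing the kinase-deficient form and clones expressing GRK2. Such a mean can be carried by only some of the conditions. A property of a single clone cannot be separated from an effect of the genotype here. TENM1, a teneurin with roles in neuronal adhesion, had the largest rise among the ranked genes (3.73 ± 0.10, adjusted p = 5.9e-09), with a mean signal of 8.32 in cultured GRK2 and 478 in cultured K220R clones. The cancer-testis antigens MAGEA6 (2.29 ± 0.14) and MAGEB2 (1.42) rose, as did the lysosomal enzyme GALC (1.92 ± 0.12), the nucleosome assembly protein NAP1L2 (1.92 ± 0.13), the transporter SLC35D2 (1.66 ± 0.08) and PIR (1.58 ± 0.06). The noncoding FAM230C also rose (1.41). CCN2, a matrix-associated growth regulator, rose by 1.31 ± 0.04 (adjusted p = 1.2e-08) and did so in all 3 growth conditions. CPEB3, which binds mRNA and regulates its translation, fell the most (-2.97 ± 0.14, adjusted p = 1.8e-07), and its other 3 tested probe sets fell too. MARVELD2, a component of tricellular tight junctions, changed by -2.56 ± 0.09, and the ADP-ribosyltransferase PARP12 by -2.39 ± 0.10. The methyltransferase EEF1AKMT1 and the chromatin-associated TOX3 (both -2.25), the Wnt receptor FZD10 (-2.11), SERP2 (-1.83), COPZ2 (-1.75), the histone H2AC6 (-1.74 ± 0.06) and the chaperone HSPA2 (-1.71) fell as well. In all, 4032 probe sets were higher and 5993 lower in K220R clones, 10025 together, and 4681 genes passed, of which 2246 had the same direction on every array. After quantile normalization 4657 were higher and 4582 lower, and with the filter at percentile 75 3614 and 3264. The total was 6032 without the mouse-expanded arrays. The genes that passed within each of the 3 conditions separately numbered 245 higher and 221 lower.

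Several fixed groups of genes moved with K220R in this mean. The YAP and TGF-beta, stress response and ERK lists below were called within cultured and within re-cultured cells, but not within mouse-expanded cells. Of the 14 YAP and TGF-beta targets, 10 rose, 0 fell and 4 did not pass (10 and 0 adjusted over the list alone, median 0.40, camera adjusted p = 6.3e-06). With CCN2, they include CCN1 (1.07 ± 0.11, adjusted p = 2.7e-05), the TGF-beta inhibitor SMAD7 (0.58) and ID2 (0.41). The adjusted p of this list was 0.042 with an estimated correlation. Of the 20 unfolded protein and integrated stress response genes, 11 rose, 1 fell and 8 did not pass (13 and 1 adjusted over the list alone, median 0.23, camera adjusted p = 2.2e-04). DNAJC3, a chaperone of the endoplasmic reticulum, rose by 0.96 ± 0.06 (adjusted p = 9.3e-07), the cystine transporter SLC7A11 by 0.75, ATF3 by 0.47 and PDIA4 by 0.43, with adjusted p = 0.046 with an estimated correlation. Of the 22 ERK response genes, 11 rose, 2 fell and 9 did not pass (12 and 2 adjusted over the list alone, median 0.28, camera adjusted p = 0.00174). FOSL1 (1.05), the phosphatase DUSP5 (0.87) and SPRED2 (0.58) rose, while MYC fell (-0.74); adjusted p = 0.058 with an estimated correlation.

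Heat shock genes and some metabolic genes also differed in the mean genotype effect. Among single conditions, the heat shock and cell cycle lists were called only in mouse-expanded cells. The cholesterol synthesis list was called only in cultured cells and the interferon list only in re-cultured cells. Of 9 heat shock response genes, 7 rose and 2 did not pass (7 adjusted over the list alone, median 0.29, camera adjusted p = 0.00174), among them BAG3 (0.40) and HSPA4L (0.48). Its adjusted p was 0.058 with an estimated correlation, and over the alternatives it ranged from 1.4e-04 to 0.150, the latter without the mouse-expanded arrays. In that setting the median of the list was 0.09. Of 16 cholesterol synthesis genes, 6 rose, 1 fell and 9 did not pass (6 and 1 adjusted over the list alone, median 0.14, camera adjusted p = 0.0266), with HMGCS1, an early enzyme of the pathway, at 0.47 and MSMO1 at 0.58. For this list the adjusted p was 0.206 with an estimated correlation and from 0.00493 to 0.185 over the alternatives, with 0.0537 without replicate 2 of cultured K220R. Of 19 interferon response genes, 1 rose, 9 fell and 9 did not pass (1 and 9 adjusted over the list alone, median -0.17, camera adjusted p = 0.0261). OAS3 (-0.91) and IFITM2 (-0.48), both antiviral factors, fell; adjusted p = 0.122 with an estimated correlation. Over the alternatives the camera adjusted p of this list was at most 0.0811. After quantile normalization it was 0.0752, with a median of -0.08. The call also ended without replicate 1 of re-cultured GRK2, with a median of -0.15. Of 31 cell cycle genes, 13 rose, 4 fell and 14 did not pass (14 and 4 adjusted over the list alone, median 0.09, camera adjusted p = 0.0448), with BIRC5 at 0.29. The adjusted p was 0.176 with an estimated correlation and from 0.00854 to 0.639 over the alternatives, the latter after quantile normalization. This call ended without replicate 2 of mouse-expanded GRK2 (0.0532), replicate 1 of mouse-expanded K220R (0.0855), replicate 1 of cultured GRK2 (0.0692), replicate 2 of cultured K220R (0.0614) or replicate 1 of re-cultured GRK2 (0.0950).

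The remaining lists were not called in the mean genotype effect. Of 22 cell adhesion and junction genes 7 rose and 2 fell (8 and 2 adjusted over the list alone, camera adjusted p = 0.0796), with the matrix protein FN1 at 1.18 ± 0.04 (adjusted p = 2.4e-08) and its receptor subunit ITGA5 at 0.59. Of 10 RGS proteins, which speed up the switching off of G proteins, 4 rose and 2 fell (4 and 2 adjusted over the list alone, camera adjusted p = 0.960), with RGS19 at -0.62, RGS2 at 0.42 and RGS4 at 0.83. Of 11 genes of the RAF MEK ERK cascade 4 rose and 1 fell (5 and 1 adjusted over the list alone, camera adjusted p = 0.234). Of 23 hypoxia response genes 7 rose and 3 fell (7 and 3 adjusted over the list alone, camera adjusted p = 0.215). One of 15 PPAR gamma targets and lipid droplet genes rose and 1 fell, as for 5 cAMP CREB response genes, and both counts were the same adjusted over the list alone (camera adjusted p = 0.895 and 0.960). Of 10 Wnt targets 1 rose and 1 fell (1 and 0 adjusted over the list alone, camera adjusted p = 0.960), and of 13 neuronal genes 2 rose and 2 fell (2 and 2 adjusted over the list alone, camera adjusted p = 0.75). The glycolysis list had 3 rises and 2 falls among 17 genes, and the fatty acid synthesis list 1 and 2 among 11 (3 and 2, and 2 and 3, adjusted over the list alone; camera adjusted p = 0.923 and 0.960). Respiratory chain genes showed 4 rises and 3 falls among 24, and renal development genes 1 and 2 among 11, unchanged adjusted over the list alone (camera adjusted p = 0.960 for both). NF-kappaB genes showed 0 rises and 2 falls among 14 (0 and 1 adjusted over the list alone, camera adjusted p = 0.960).

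None of the lists of other cell types was called in this mean. Members that rose and fell numbered 1 and 2 of 9 for fibroblast and matrix, 0 and 1 of 5 for endothelium, 0 and 1 of 7 for leukocyte and macrophage, 0 and 0 of 3 for red cell, 1 and 1 of 3 for adipocyte, 3 and 0 of 8 for skeletal muscle, and 1 and 0 of 3 for keratinocyte. These counts were the same adjusted over the list alone except for keratinocyte (2 and 0), and the camera adjusted p lay between 0.254 for skeletal muscle and 0.960. Median, mean and test direction differed in sign for 6 lists in this comparison. The medians were above 0 and the means below it for GPCR kinases, NF-kappaB genes, renal development genes and leukocytes, where the test pointed up only for GPCR kinases. For fatty acid synthesis and respiratory chain genes both were below 0 and the test pointed up.

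Within mouse-expanded cells the question was how clones that express GRK2 or its K220R form differ during growth in an animal. The signal of the brightest GRK2 probe set also differed here (1877 in GRK2 and 6370 in K220R clones). The form of GRK2 is therefore not separated from the level of this signal. TENM1 (3.50 ± 0.18), MAGEA6 (2.74), the nucleoside enzyme CDA (2.29), LYPD3 (2.26) and the transcription factor KLF2 (2.03 ± 0.13, adjusted p = 1.7e-06) were higher in K220R clones. CCN2 was higher by 2.03 ± 0.08 (adjusted p = 6.4e-08). CPEB3 was lower by the largest amount (-3.98 ± 0.24, adjusted p = 1.2e-06), followed by the pseudogene NACA4P (-2.96 ± 0.08), PARP12 (-2.96), MARVELD2 (-2.90), the noncoding RNA LINC00632 (-2.87) and FZD10 (-2.82). Of 9 heat shock response genes, 7 rose and 2 did not pass (7 adjusted over the list alone, median 0.63, camera adjusted p = 0.00155), among them the chaperones HSPE1 (0.70), HSPH1 (0.63) and HSPB1 (0.77); adjusted p = 0.161 with an estimated correlation. Of 31 cell cycle genes 14 rose and 1 fell (15 and 2 adjusted over the list alone, median 0.23, camera adjusted p = 0.0131), such as the mitotic kinase AURKA (0.61) and BIRC5 (0.53). Its adjusted p was 0.187 with an estimated correlation, 0.512 after quantile normalization and 0.0627 without replicate 1 of mouse-expanded K220R, within a range from 7.4e-04 to 0.512. The skeletal muscle list had 3 rises among 8 members, CKM at 1.15 and MYL11 at 1.69 included, and was not called (4 adjusted over the list alone, camera adjusted p = 0.172).

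In this comparison 3676 probe sets were higher and 6156 lower in K220R clones, 9832 together. The count was 6287 without replicate 2 of mouse-expanded GRK2 and 6093 without replicate 1 of mouse-expanded K220R. The total was 6043 with the filter at percentile 75. The side with more probe sets turned in 3 settings, with 4582 higher and 4466 lower after quantile normalization, 2250 and 1714 with 1 probe set per gene, and 3452 and 2591 with the filter at percentile 75. Among changes of at least 2-fold, 169 were higher and 2374 lower, and the arrays of mouse-expanded GRK2 clones are those with the raised median signal (47.8 and 48.3). Such falls were seen in 27.3% of the 4111 tested probe sets with no gene listed and in 3.79% of the 25066 for protein-coding genes. Quantile normalization moved the median difference of all tested probe sets from -0.09 to 0.04 here, from 0.08 to -0.04 between mouse-expanded and re-cultured cells, and from -0.07 to 0.04 for the interaction of mouse-expanded and cultured cells. Changes of that size are not distinguished from the scaling.

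In cultured cells, where neither genotype had been in a mouse, TENM1 (4.35 ± 0.18, adjusted p = 1.9e-07), NAP1L2 (2.66), GALC (2.32) and PIR (2.09 ± 0.10) were again higher in K220R clones. The G protein subunit GNAO1 was higher by 2.44 ± 0.54 (adjusted p = 0.019), but did not pass without replicate 1 or 2 of cultured GRK2 (adjusted p = 0.12 and 0.083) or replicate 1 or 2 of cultured K220R (0.11 and 0.092), the range over its alternatives being 4.8e-04 to 0.12. Lower in K220R clones were TOX3 (-2.51 ± 0.31), EEF1AKMT1 (-2.51), the retinol carrier RBP4 (-2.47 ± 0.14), H2AC6 (-2.46 ± 0.11, adjusted p = 4.0e-07), MARVELD2 (-2.38) and SERP2 (-2.31). Of 20 stress response genes, 7 rose and 13 did not pass (11 adjusted over the list alone, median 0.30, camera adjusted p = 2.1e-05), with DNAJC3 at 0.93 and SLC7A11 at 0.88; adjusted p = 0.046 with an estimated correlation. Of 14 YAP and TGF-beta targets 4 rose (4 adjusted over the list alone, median 0.15, camera adjusted p = 0.0016), CCN2 by 0.85 and ID2 by 0.83, with adjusted p = 0.089 with an estimated correlation. Of 16 cholesterol synthesis genes 3 rose and 1 fell (7 and 1 adjusted over the list alone, median 0.25, camera adjusted p = 0.00179), HMGCS1 by 0.76, and adjusted p = 0.159 with an estimated correlation.

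ERK response genes in culture numbered 6 higher and 1 lower of 22 (6 and 1 adjusted over the list alone, median 0.21, camera adjusted p = 0.0446). For this list the adjusted p was 0.168 with an estimated correlation and from 0.0149 to 0.166 over the alternatives. The call ended without replicate 2 of cultured GRK2, where the median was 0.19, and without replicate 1 of cultured K220R, where it was 0.10. FOSL1 (1.03) and DUSP5 (0.82) rose, and MYC fell (-1.30 ± 0.08, adjusted p = 4.3e-06). Cultured cells had 1092 probe sets higher and 1197 lower, 2289 together, a near balance that tipped the other way with the filter at percentile 75 (1210 and 1206). Without the intensity trend the total was 1423. In place of 2289 there were 789 without replicate 1 and 885 without replicate 2 of cultured GRK2, and 804 without replicate 1 and 812 without replicate 2 of cultured K220R.

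In re-cultured cells the comparison asked which genotype differences are present after passage through the mouse. MAGEA6 (3.49 ± 0.25, adjusted p = 1.2e-05), TENM1 (3.35 ± 0.18), GALC (2.48), MAGEB2 (2.38) and NAP1L2 (2.25) were higher in K220R clones. EGFR, the receptor of epidermal growth factor, had the largest fall (-2.84 ± 0.76, adjusted p = 0.027), but 0 of its other 5 probe sets fell and 1 was higher, and the call ended without replicate 1 of re-cultured GRK2 (-1.39, adjusted p = 0.177), replicate 1 of re-cultured K220R (0.0664) or replicate 2 of re-cultured K220R (0.143), in a range from 0.00107 to 0.177. CPEB3 (-2.76), H2AC6 (-2.47 ± 0.11, adjusted p = 6.4e-07), MARVELD2 (-2.39), PARP12 (-2.19) and EEF1AKMT1 (-2.09) were lower. Of 14 YAP and TGF-beta targets, 7 rose and 7 did not pass (10 adjusted over the list alone, median 0.57, camera adjusted p = 8.7e-07): CCN1 rose by 1.52, the actin-binding TAGLN by 1.17, CCN2 by 1.06 and ID2 by 0.81, with adjusted p = 0.030 with an estimated correlation. Of 20 stress response genes 8 rose (10 adjusted over the list alone, median 0.23, camera adjusted p = 2.4e-04), SLC7A11 by 1.38 and the amino acid enzyme ASNS by 0.47, with adjusted p = 0.047 with an estimated correlation. Of 22 ERK response genes 10 rose and 2 fell (12 and 2 adjusted over the list alone, median 0.44, camera adjusted p = 0.00249), DUSP5 by 1.20 and DUSP4 by 0.96, while MYC was at -0.74. The adjusted p was 0.066 with an estimated correlation, and from 3.8e-04 to 0.120 over the alternatives, the latter with the filter at percentile 75.

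Hypoxia response genes were 5 higher and 0 lower of 23 in re-cultured cells (7 and 0 adjusted over the list alone, median 0.15, camera adjusted p = 0.00736), with the glucose transporter SLC2A3 at 0.91 and the peptide hormone ADM at 0.95; adjusted p = 0.122 with an estimated correlation. Interferon response genes were 0 higher and 6 lower of 19 (2 and 7 adjusted over the list alone, median -0.24, camera adjusted p = 0.0133), with IFITM2 at -0.71 and OAS3 at -0.88. Its adjusted p was 0.115 with an estimated correlation and 0.0704 without replicate 1 of re-cultured GRK2, the highest of a range that began at 0.00108. There were 2388 probe sets higher and 2599 lower, 4987 together, against 2403 and 2313 after quantile normalization. Fitted on only its own 4 arrays, the comparison had 1099 calls. In place of 4987 there were 3237 without replicate 1 of re-cultured GRK2, 2738 without replicate 1 of re-cultured K220R and 2379 without replicate 2 of re-cultured K220R. The re-cultured GRK2 pair also had the lowest correlation between replicates (0.978), so p-values from the spread shared by all groups may be too small here.

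The genotype effects in the 3 growth conditions, which share no arrays, were compared across 13946 genes. The correlation across genes was 0.30 between mouse-expanded and cultured cells (rho 0.30), 0.32 between mouse-expanded and re-cultured cells (rho 0.30) and 0.44 between cultured and re-cultured cells (rho 0.39). These are 3 of 5 correlations computed, and genes are not independent replicates. The same clones may have been used in all 3 conditions, so stable differences between clones would also give such agreement. In cultured and re-cultured cells 335 genes were higher in both, against 51.5 for independent lists, and 394 were lower in both, against 70.3. Of 742 genes that passed in both, 98.2% had the same direction. For mouse-expanded and cultured cells 385 were higher in both (106 for independent lists) and 319 lower (89.2), with 90% of 782 in the same direction. For mouse-expanded and re-cultured cells these values were 539 (184), 489 (182) and 84.5% of 1217.

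Interactions tested where the genotype effect itself differed between conditions. CCN2 had a larger K220R rise in mouse-expanded than in cultured cells (1.18 ± 0.11, adjusted p = 7.4e-05), and KLF2 (2.31) and the gap junction gene GJB2 (2.29) differed in the same way, while the Wnt target LGR5 differed by -2.77. Between mouse-expanded and re-cultured cells the K220R effect was higher for MYL11 (2.44) and for the immediate early gene FOS (2.35 ± 0.25, adjusted p = 1.7e-04). Between re-cultured and cultured cells it was higher for RBP4 (1.67). In the interaction of mouse-expanded and cultured cells 1426 probe sets were positive and 2845 negative, 4271 together. The excess of negative ones shrank after quantile normalization (1639 and 2146) and turned with 1 probe set per gene (774 and 581) and with the filter at percentile 75 (1476 and 1312), and protein-coding genes alone gave 2654 calls. In place of 4271 there were 2584 and 2528 without replicate 1 and replicate 2 of mouse-expanded GRK2, 2507 and 2781 without those of mouse-expanded K220R, 2480 and 2481 without those of cultured GRK2, and 2292 and 2507 without those of cultured K220R. Between re-cultured and cultured cells 318 passed, 174 positive and 144 negative, against 67 and 106 with 1 probe set per gene. The total was 189 without a filter, 55 without the intensity trend and 82 with only the arrays compared. In place of 318 there were 53 and 89 without replicate 1 and replicate 2 of cultured GRK2, without those of cultured K220R 69 and 64, without replicate 2 of re-cultured GRK2 2297, and without those of re-cultured K220R 129 and 107. Between mouse-expanded and re-cultured cells 5564 passed, 2082 positive and 3482 negative, though 1229 and 734 with 1 probe set per gene and 2078 and 1745 with the filter at percentile 75. In place of 5564 there were 3687 and 3567 without replicate 1 and replicate 2 of mouse-expanded GRK2 and 3444 without replicate 1 of mouse-expanded K220R.

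Mouse-expanded and cultured clones were compared to find what growth in the animal changes, averaged over both genotypes. Samples of mouse-expanded clones may hold RNA of mouse host cells, which was not excluded as a source of the differences below. HBE1, the embryonic beta-like globin, rose by 8.02 ± 0.14 (adjusted p = 7.0e-12), from a signal of 3.42 in cultured to 4317 in mouse-expanded GRK2 clones. Its other probe set was too dim to be tested. The matrix protein THBS2 (5.66 ± 0.09), C11orf96 (5.57 ± 0.06), the dynein chain DNAH17 (5.26), the activin subunit INHBA (5.25 ± 0.20, adjusted p = 3.0e-09), the interleukin-13 decoy receptor IL13RA2 (5.23 ± 0.12) and the protease MMP10 (4.95 ± 0.14) rose. The early embryo genes KHDC1L (5.17), MBD3L2 (5.10) and PRAMEF12 (4.85) did so too. HMGA2, a chromatin protein of embryonic and dividing cells, fell the most (-3.94 ± 0.05, adjusted p = 2.0e-13). The inhibitors of differentiation ID1 (-3.54 ± 0.07, adjusted p = 2.0e-11) and ID3 (-2.58), the synaptic SLITRK5 (-3.31), the receptor KIT (-2.82 ± 0.12), the protocadherin PCDH7 (-2.73), CCN2 (-2.54 ± 0.05) and cyclin D1, CCND1 (-2.43 ± 0.08), fell as well. There were 7098 probe sets higher and 6551 lower, 13649 together. The larger side turned after quantile normalization (6163 higher and 7567 lower), with the filter at percentile 75 (4156 and 5266) and in K220R clones only (4856 and 5599). Of 7005 genes that passed, 5937 had the same direction on every array. The growth effect of GRK2 clones and that of K220R clones, which share no arrays, correlated at 0.75 across genes (rho 0.62). Of 3493 genes that passed in both genotypes 95.2% had the same direction, with 1768 higher in both (597 for independent lists) and 1556 lower (499).

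Genes of cell division fell together in mouse-expanded cells. Of 31 cell cycle genes 26 fell, 0 rose and 5 did not pass (26 adjusted over the list alone, median -0.43, camera adjusted p = 5.2e-09), among them AURKA (-1.04 ± 0.04, adjusted p = 6.0e-09), PLK1 (-1.14) and CCNA2 (-0.77); adjusted p = 0.015 with an estimated correlation. Of 24 respiratory chain genes 22 fell (22 adjusted over the list alone, median -0.33, camera adjusted p = 4.1e-07), such as ATP5MC1 (-0.74), CYC1 (-0.71) and SDHC (-0.67), with adjusted p = 0.118 with an estimated correlation. Of 16 cholesterol synthesis genes 2 rose and 11 fell (2 and 13 adjusted over the list alone, median -0.65, camera adjusted p = 2.5e-05): INSIG1 (-1.44), SC5D (-1.21) and DHCR7 (-0.98) fell, and adjusted p = 0.046 with an estimated correlation. Of 11 fatty acid synthesis genes 7 fell and 0 rose (7 and 1 adjusted over the list alone, median -0.39, camera adjusted p = 0.0078), with the desaturase SCD at -1.69 ± 0.04 (adjusted p = 1.1e-10) and its regulator SREBF1 at -1.56; adjusted p = 0.081 with an estimated correlation.

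Inflammatory, signalling and neuronal genes rose in mouse-expanded cells. Of 14 NF-kappaB and inflammatory genes 10 rose and 4 did not pass (10 adjusted over the list alone, median 0.93, camera adjusted p = 2.4e-04): the chemokine CXCL8 (2.15), RELB (1.82), LIF (1.56) and NFKBIA (1.26), with adjusted p = 0.046 with an estimated correlation. Of 19 interferon response genes 11 rose and 2 fell (11 and 2 adjusted over the list alone, median 0.60, camera adjusted p = 0.00356), IFI27 by 4.68 and BST2 by 3.06, with adjusted p = 0.0595 with an estimated correlation. Of 22 ERK response genes 13 rose and 3 fell (15 and 4 adjusted over the list alone, median 0.71, camera adjusted p = 0.00807): FOS rose by 4.24 and DUSP5 by 1.99, against HMGA2 and CCND1, which fell, and adjusted p = 0.069 with an estimated correlation. Of 13 neuronal genes of HEK cells 10 rose and 3 did not pass (12 adjusted over the list alone, median 1.09, camera adjusted p = 2.3e-05): STMN4 (3.11), ELAVL3 (2.62), GAP43 (1.40) and ENO2 (1.14), with adjusted p = 0.046 with an estimated correlation.

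Markers of other cell types moved with expansion in the mouse, and RNA of mouse host cells was not excluded as their source. Only 8 of 14 listed skeletal muscle genes and 7 of 15 leukocyte and macrophage genes were tested, with mean log2 levels of 5.74 and 5.73. Of 13 listed fibroblast and matrix genes 9 were tested. Members so dim may have passed the filter only through arrays where they were high, so the shares that rose may be too large. Of 8 skeletal muscle genes 5 rose (5 adjusted over the list alone, median 1.63, camera adjusted p = 0.0065), CKM by 3.11, TNNC2 by 2.22 and ACTA1 by 2.09; adjusted p = 0.069 with an estimated correlation. Of 7 leukocyte and macrophage genes 5 rose (6 adjusted over the list alone, median 1.05, camera adjusted p = 0.0192), with CD74 at 2.98 and LAPTM5 at 1.05. For this list the adjusted p was 0.188 with an estimated correlation and from 0.00418 to 0.0811 over the alternatives, the latter in K220R clones only. Of 9 fibroblast and matrix genes 7 rose and 2 fell (7 and 2 adjusted over the list alone, median 1.14, camera adjusted p = 0.0205): the collagens COL1A2 (3.38) and COL3A1 (2.26) rose and SPARC fell (-0.68), with adjusted p = 0.355 with an estimated correlation. Endothelium had 2 rises and 2 falls of 5 (camera adjusted p = 0.564), red cell 1 and 0 of 3 (0.357), adipocyte 1 and 1 of 3 (0.993) and keratinocyte 1 and 0 of 3 (0.186), unchanged adjusted over the list alone. The adipocyte list had a median of -0.15 and a mean of 0.99, since the gluconeogenic enzyme PCK1 rose by 4.30.

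Other lists moved both ways in mouse-expanded cells and were not called. YAP and TGF-beta targets had 5 rises and 7 falls among 14 (5 and 7 adjusted over the list alone, camera adjusted p = 0.351), with PMEPA1 at 2.03 against ID1 and CCN2, which fell. Stress response genes had 9 rises and 8 falls among 20 (9 and 8 adjusted over the list alone, camera adjusted p = 0.970), ATF3 at 2.01 and the serine synthesis enzymes PHGDH and PSAT1 each at -1.28, with a median above 0 and a mean below it. Hypoxia response genes had 9 rises and 4 falls among 23 (9 and 4 adjusted over the list alone, camera adjusted p = 0.465), with ANKRD37 at 2.24. Cell adhesion genes had 11 rises and 6 falls among 22 (11 and 6 adjusted over the list alone, camera adjusted p = 0.564), with a rise of the transcription factor SNAI2 and the keratin KRT8 at -1.01.

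Re-cultured and cultured clones were compared to find what differs in culture after a passage through the mouse. IL13RA2 was higher by the largest amount (adjusted p = 7.5e-10), with signals of 493 and 1109 in re-cultured GRK2 and K220R clones against 8.90 and 6.95 in culture. The cytokine IL32 (3.94 ± 0.11, adjusted p = 2.0e-09), the desmosome protein PKP3 (2.50 ± 0.12), C12orf56 (2.37), ICAM2 (2.26), MAGEA6 (2.22), the noncoding PURPL (2.06), KHDC1L (1.99), the antigen presentation chaperone CD74 (1.94 ± 0.12, adjusted p = 8.8e-07) and the p53 target TP53I3 (1.92) were higher too. The cadherin FAT3 (-2.17 ± 0.09), the mRNA export factor ALYREF (-2.15 ± 0.06, adjusted p = 2.2e-09), ANKRD36B (-1.82), the guidance cue SLIT2 (-1.79 ± 0.05, adjusted p = 1.1e-09), RASAL2 (-1.76), the interferon-induced IFI6 (-1.69 ± 0.21), the G protein subunit GNG4 (-1.64), KCNQ1OT1 (-1.60) and the splicing factor HNRNPL (-1.54 ± 0.09) were lower. There were 3530 probe sets higher and 5071 lower, 8601 together. This excess of falls nearly vanished after quantile normalization (3999 and 4149) and turned with 1 probe set per gene (1940 and 1653) and with the filter at percentile 75 (3153 and 2932). In K220R clones only, 4895 passed. Of 3662 genes that passed, 2995 had the same direction on every array. The effect in GRK2 clones correlated with that in K220R clones at 0.47 across genes (rho 0.42), and 97.4% of 853 genes that passed in both had the same direction. Of these, 467 were higher in both (98.9 for independent lists) and 364 lower (69.5).

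Signalling and stress genes were higher in re-cultured than in cultured cells. Of 22 ERK response genes 17 rose and 1 fell (17 and 2 adjusted over the list alone, median 0.50, camera adjusted p = 4.7e-07): FOS by 1.68, the ETS factor ETV5, IER3 by 0.92 and DUSP5 by 0.80, with adjusted p = 0.023 with an estimated correlation. Of 14 NF-kappaB and inflammatory genes 9 rose (9 adjusted over the list alone, median 0.50, camera adjusted p = 7.3e-05), such as CCL2 (1.31) and CXCL8 (1.02), with adjusted p = 0.042 with an estimated correlation. Of 20 stress response genes 14 rose and 3 fell (16 and 3 adjusted over the list alone, median 0.26, camera adjusted p = 9.8e-04): CHAC1 at 0.98 and ATF3 at 0.53 rose and SESN2 fell (-0.76), with adjusted p = 0.0513 with an estimated correlation. Of 9 heat shock genes 4 rose (5 adjusted over the list alone, median 0.13, camera adjusted p = 0.0087), HSPH1 by 0.80 and CHORDC1 by 0.63. The adjusted p was 0.107 with an estimated correlation and from 0.00276 to 0.108 over the alternatives, the latter in K220R clones only.

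Fatty acid synthesis genes were lower in re-cultured cells, with 5 falls and 0 rises among 11 (5 adjusted over the list alone, median -0.18, camera adjusted p = 0.0211), SREBF1 at -0.88 and SCD at -0.34. Its adjusted p was 0.171 with an estimated correlation, and without replicate 1 of cultured K220R it was 0.0536, the highest of a range from 0.00582. Of 5 endothelium genes 3 fell (3 adjusted over the list alone, median -0.43, camera adjusted p = 0.0211); EGFL7 (-0.59) did not pass in K220R clones only (adjusted p = 0.258, the highest of a range from 9.7e-04). For this list the adjusted p was 0.326 with an estimated correlation, 0.0571 without replicate 1 of re-cultured GRK2 and 0.346 in K220R clones only, within a range from 0.00446 to 0.346. Cell cycle genes, with 1 rise and 5 falls among 31 (1 and 4 adjusted over the list alone, camera adjusted p = 0.317), and respiratory chain genes, with 0 rises and 2 falls among 24 (0 and 2 adjusted over the list alone, camera adjusted p = 0.986), were not called. Skeletal muscle (2 rises of 8), leukocyte and macrophage (1 rise of 7) and fibroblast and matrix genes (1 fall of 9) were not called either (camera adjusted p = 0.262, 0.652 and 0.559), with counts unchanged adjusted over the list alone.

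Mouse-expanded and re-cultured clones were compared to find what differs between growth in the animal and culture after such expansion. HBE1 (8.03 ± 0.14), DNAH17 (4.93), PCK1 (4.88 ± 0.12, adjusted p = 2.0e-10), LCAL1 (4.80), THBS2 (4.75) and PRAMEF12 (4.65) were higher in the mouse-expanded state, and HMGA2 (-3.66 ± 0.05), ID1 (-3.29), CCN2 (-3.21 ± 0.05) and CCND1 (-2.67) were lower. GRK2 was lower as well (-0.39 ± 0.09, adjusted p = 0.0035), but higher by 0.90 in K220R clones only. Of 31 cell cycle genes 24 fell (24 adjusted over the list alone, median -0.35, camera adjusted p = 2.8e-07), AURKA by 0.98 (-0.98), with adjusted p = 0.027 with an estimated correlation. Of 24 respiratory chain genes 23 fell (23 adjusted over the list alone, median -0.36, camera adjusted p = 4.3e-07), CYC1 at -0.69, with adjusted p = 0.177 with an estimated correlation. Of 16 cholesterol synthesis genes 1 rose and 11 fell (1 and 11 adjusted over the list alone, median -0.41, camera adjusted p = 4.3e-04), with adjusted p = 0.118 with an estimated correlation. Of 13 neuronal genes 10 rose (10 adjusted over the list alone, median 0.89, camera adjusted p = 4.0e-04), and adjusted p = 0.114 with an estimated correlation. There were 9766 probe sets higher and 6996 lower, 16762 together, but 7553 and 8726 after quantile normalization and 4758 and 5798 with the filter at percentile 75. Of 7756 genes that passed, 6093 had the same direction on every array.

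Some lists called between mouse-expanded and re-cultured cells depended on the setting. Interferon response genes were 11 higher and 1 lower of 19 (11 and 1 adjusted over the list alone, median 0.45, camera adjusted p = 0.0233), with IFI27 at 3.68 and BST2 at 1.85; adjusted p = 0.148 with an estimated correlation, and from 0.00625 to 0.0502 over the alternatives. Glycolysis genes were 2 higher and 10 lower of 17 (2 and 10 adjusted over the list alone, median -0.24, camera adjusted p = 0.0233), with GPI at -0.71; adjusted p = 0.494 with an estimated correlation, and from 0.0066 to 0.174 over the alternatives, the latter after quantile normalization. The neuronal list reached 0.0659 with the filter at percentile 75, in a range from 2.0e-04. Skeletal muscle (6 of 8 higher, median 1.28, camera adjusted p = 0.0213), leukocyte and macrophage (6 of 7 higher, median 0.92, 0.0233) and fibroblast and matrix genes (7 higher and 2 lower of 9, median 1.30, 0.0213) were also higher, with unchanged counts adjusted over the list alone, and CKM at 1.95 and COL1A2 at 3.43. Dim members may again have entered the muscle and leukocyte lists only through arrays where they were high. The adjusted p values of the muscle, leukocyte and fibroblast lists were 0.148, 0.225 and 0.282 with an estimated correlation. Over the alternatives they were at most 0.0633 for muscle, 0.220 for leukocytes and 0.0388 for fibroblasts.

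**Figure D3:**
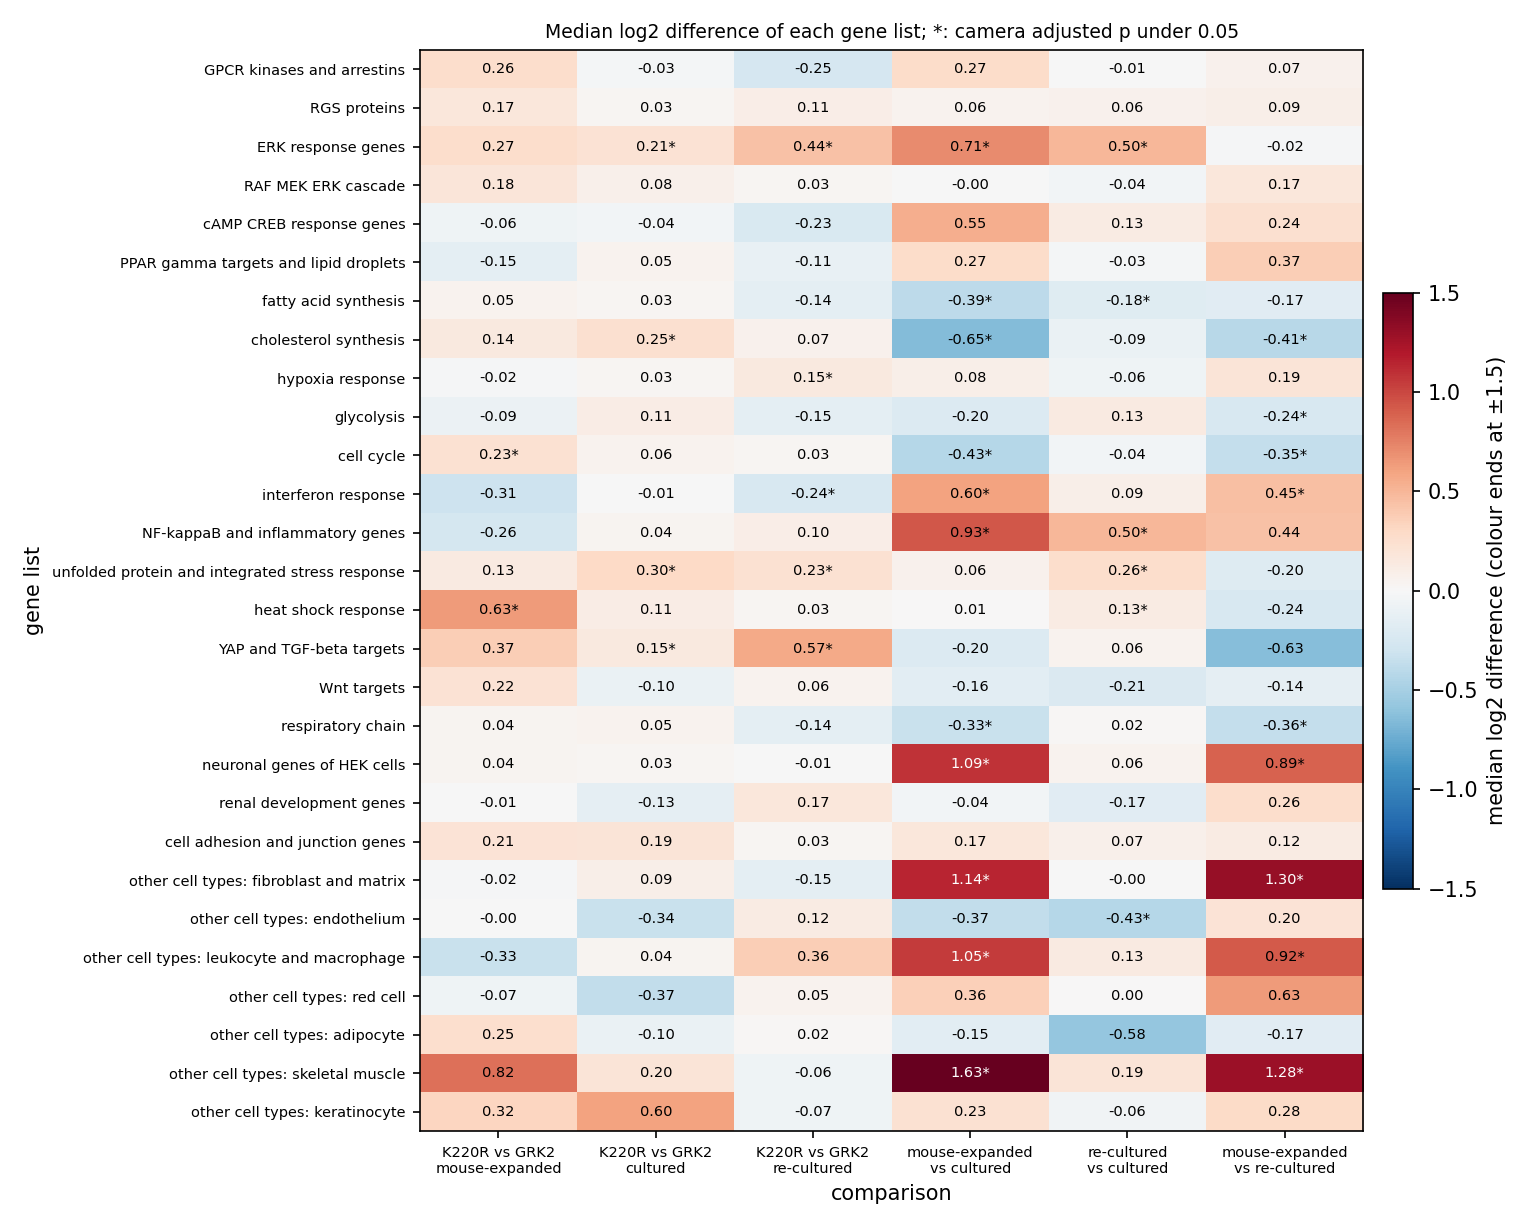
Median log2 difference of the tested members of each of the 28 gene lists (y axis) in 6 comparisons (x axis), printed in each cell and shown in colour, with * for a camera adjusted p under 0.05 at the preset correlation. The cell cycle list is at -0.43 and the NF-kappaB list at 0.93 in mouse-expanded against cultured cells.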

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

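The tests on the GRK2 probe set, the comparison limited to protein-coding genes and the reading of the scaling test by leaving out arrays were chosen only after the result was seen, and the tests on probe set level were set once the unmatched shares were known. The results below were taken up because the K220R effect differed between growth conditions in an interaction test.

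The genotype effect differed in 4271 probe sets between mouse-expanded and cultured cells, in 318 between re-cultured and cultured cells and in 5564 between mouse-expanded and re-cultured cells. Other splits of the arrays were tested against the real ones, but a split that parts the replicates of a group gives few calls by construction, and few splits keep them together, so if the replicates are technical a chance arrangement of the groups is not excluded. In an additive model 5587 probe sets differed between genotypes, and 2 of 100 splits drawn from 462, the real one included, gave as many. The highest other split had 5711, with mouse-expanded GRK2 and all cultured arrays on one side, which points to a structure of the samples: the genotype difference in mouse-expanded cells. For mouse-expanded against cultured arrays the real split gave 11337 and the highest other 271, for re-cultured against cultured 6271 and 0, and for mouse-expanded against re-cultured 12451 and 0, with 1 of 34 splits as large in each.

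The K220R falls of at least 2-fold in mouse-expanded cells outnumbered the rises, 2374 to 169, a ratio of 14.0. After quantile normalization the ratio was 3.14 (1368 to 435), between 2.44 and 3.35 with 1 array left out, so the scaling of the arrays may account for a part whose size stays open, while 3.14 is still far from balance. At the same level in cultured arrays, 27.3% of probe sets with no gene listed fell, against 6.0% of protein-coding ones, a ratio of 4.55. The first share equals the unmatched one by construction, and the protein-coding share was 3.79% before matching. Levels in the mouse-expanded arrays were not matched. Genomic DNA or background in the mouse-expanded GRK2 arrays stays open, since probe sets with no gene listed can report sequence outside exons. In 30.1% of 522 genes whose dimmest probe set fell the brightest fell too (157), with 58 higher, against 12.1% in other such genes. Unspliced or intron-retaining RNA in the mouse-expanded GRK2 arrays is a candidate explanation. The share does not test it, because raised background would also spare bright probe sets. Other isoforms or weak probe sets could give the same. Sequencing of the same RNA with and without DNase treatment would tell these apart.

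The K220R effect on the GRK2 probe set differed by 1.64 between mouse-expanded and cultured cells, by -0.94 between re-cultured and cultured cells and by 2.58 between mouse-expanded and re-cultured cells. A swap of genotype labels in the re-cultured arrays can be excluded, because the K220R effects in cultured and re-cultured cells correlated at 0.44 across genes where a swap would make them negative. For the other probe set of middle level the K220R difference in mouse-expanded cells was 0.092 ± 0.24. That probe set passed in no comparison, so it is not known whether it can report a change of GRK2. A change of the whole endogenous transcript therefore stays open. Whether other genes follow this GRK2 level stays open, because stable differences between the clones can hold the correlation of K220R effects across genes between mouse-expanded and re-cultured cells (0.32) above 0, and 189 of 1217 genes that passed in both had opposite directions. Probe set positions and the transfected sequence were not analysed here, so the source of the signal stays open, and amplification across the construct junction would tell the transcripts apart.

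Between mouse-expanded and cultured cells the K220R effect differed most upward for EEF2KMT (2.80), TNNC1 (2.37) and CYP26A1 (2.34). It differed most downward for LINC00632 (-3.20), NACA4P (-3.01) and GNAO1 (-2.99). The calls of EEF2KMT and GNAO1 each ended in 8 of 19 alternative settings, with adjusted p values from 0.00597 to 0.120 and from 0.00794 to 0.0773.

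Between re-cultured and cultured cells the differences were 2.84 for MAGEA6, 2.03 for CKM, 1.70 for CCDC144NL-AS1, -1.81 for DTNB, -1.71 for MLLT3 and -1.51 for TOR4A. Each of these 6 calls ended in at least 1 alternative setting, with highest adjusted p values of 0.118, 0.0844, 0.144, 0.169, 0.0892 and 0.139. Between mouse-expanded and re-cultured cells EGFR differed by 3.41 (call ended in 14 of 19 settings, adjusted p from 0.00214 to 0.166), SLC5A2 by 2.65, NACA4P by -3.05, LINC00632 by -2.81 and GINS4 by -2.66.

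Among lists, the K220R effect on cholesterol synthesis genes was lower in re-cultured than in cultured cells (median -0.20, camera adjusted p = 0.0144), with adjusted p = 0.298 with an estimated correlation and 0.0543 without replicate 1 of re-cultured K220R. That on YAP and TGF-beta targets was higher (median 0.32, camera adjusted p = 0.0228), with adjusted p = 0.298 with an estimated correlation and at most 0.0893, with the filter at percentile 75. This call also ended without replicate 1 of re-cultured GRK2 (median 0.17) or of re-cultured K220R (median 0.21). That on respiratory chain genes was lower (median -0.21, camera adjusted p = 0.0144), with adjusted p = 0.478 with an estimated correlation, and 0.0776 and 0.0543 without the same arrays. After quantile normalization the respiratory chain median was -0.11 and the adjusted p 0.286, the highest of a range from 0.00362. Between mouse-expanded and re-cultured cells the effect on heat shock genes was higher (median 0.39, camera adjusted p = 0.0381), with adjusted p = 0.331 with an estimated correlation and from 0.00863 to 0.104 over the alternatives. That call ended without replicate 1 of mouse-expanded GRK2 (0.0610), of mouse-expanded K220R (0.0550) or of re-cultured K220R (0.0547).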

How the results depend on the processing

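Leaving the mouse-expanded arrays out of the mean genotype effect, testing growth in K220R clones only and testing protein-coding genes only were chosen only after the result was seen. Only named genes and lists already called in the main fit, and GRK2, were followed, so the counts below do not describe weaker results. Of 7911 gene results under settings other than leaving out 1 array, 7551 stayed on the same side of the threshold. Of the rest, 356 lost their call and 4 changed sign. Of 515 list results 481 stayed on the same side and 34 lost their call. A result on the same side was counted as unchanged whatever the size of its effect. With 1 array left out, a larger share of gene results lost the call, though not of list results.

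The results that changed sign were GRK2 in the mean genotype effect without mouse-expanded arrays (-0.35, adjusted p = 0.0183), and, in K220R clones only, GRK2 in mouse-expanded against re-cultured cells (0.90), FLT1 in mouse-expanded against cultured cells (-0.29) and HSPB1 in re-cultured against cultured cells (-0.14). GRK2 follows from its genotype effects, which have opposite signs in these conditions. For FLT1 and HSPB1 the cause was not tested.

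Counts of probe sets also moved. Without a filter the interaction of re-cultured and cultured cells had 189 calls in place of 318. With the filter at percentile 75 there were 6043 for K220R in mouse-expanded cells, 10556 for mouse-expanded against re-cultured cells and 2788 for the interaction of mouse-expanded and cultured cells, from a smaller set of probe sets. Without the intensity trend K220R in culture had 1423 and the interaction of re-cultured and cultured cells 55; the cause was not tested.

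With 1 probe set per gene, and so fewer probe sets, the counts were 4734, 3964, 1509 and 2701 for K220R in the mean, mouse-expanded, cultured and re-cultured cells. They were 7168, 3593 and 7788 for mouse-expanded against cultured, re-cultured against cultured and mouse-expanded against re-cultured cells. The interactions, in the order mouse-expanded minus cultured, re-cultured minus cultured and mouse-expanded minus re-cultured, had 1355, 173 and 1963. With a 2-fold change also asked, the same comparisons in the same order gave 162, 2543, 261, 575, 1877, 742, 2626, 1997, 116 and 2312.

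With only the arrays of the groups compared, there were 1099 calls for K220R in re-cultured cells and 82 for the interaction of re-cultured and cultured cells. The same setting raised the counts for K220R in mouse-expanded (10492) and cultured cells (3286) and for the interaction of mouse-expanded and cultured cells (6118). Fewer samples alone therefore do not account for the lower counts. Replicates differed more within re-cultured groups (SD of the log2 difference 0.406 for GRK2 and 0.329 for K220R) than within the others (0.293 to 0.304). The spread shared by all groups may thus be too small for re-cultured cells and too large for the others. Whether this accounts for the counts was not tested. The mean genotype effect without mouse-expanded arrays had 6032, re-cultured against cultured cells in K220R clones only 4895, and the interaction of mouse-expanded and cultured cells among protein-coding genes 2654.

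When 1 array is left out, the lone sample of its group is assumed to vary like the other groups. K220R in the mean then had 8155 (without replicate 2 of cultured K220R) to 11448 calls (without replicate 2 of re-cultured GRK2). In mouse-expanded cells it had 6093 to 6725 (without replicate 1 and replicate 2 of mouse-expanded K220R), in culture 789 to 885 (without replicate 1 and replicate 2 of cultured GRK2), and in re-cultured cells 2379 (without replicate 2 of re-cultured K220R) to 6958 (without replicate 2 of re-cultured GRK2). The growth comparisons had 11619 to 11905, 6277 to 9963 and 14901 to 16884. The interactions had 2292 to 2781, 53 to 2297 and 3444 to 7348, with both last maxima without replicate 2 of re-cultured GRK2.

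With the replicate number as a block the counts were 9627, 9476, 1991, 4625, 13394, 8284, 16547, 3897, 220 and 5259 in the order above. Correlations of replicate residuals between groups lay between -0.061 and 0.066, with 0 of 15 pairs over 0.1, so the replicate numbers do not pair the arrays. Signals near background limit what a fold of dim probe sets can show, and no detection calls were used here.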

Other observations

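The early embryo list and all tests on it were chosen only after the result was seen. A set of genes known from the early embryo, many of them targets of the transcription factor DUX4, was higher in mouse-expanded cells. Of 37 genes listed, most of the untested ones had no probe set assigned to them alone and 3 others were too dim to be tested. All 13 tested genes were higher than in culture (median 2.93), which describes rather than tests them, as each had been seen before the list was written. ZSCAN4, active at the first divisions of the embryo, rose by 3.64 ± 0.22 (adjusted p = 1.3e-07), KHDC1L by 5.17 ± 0.06, MBD3L2 by 5.10 ± 0.12, PRAMEF12 by 4.85 and the germline cyclin CCNA1 by 2.84 ± 0.16 (adjusted p = 6.3e-08). In mouse-expanded cells 11 of the 13 were lower in K220R than in GRK2 clones (median -1.62), ZSCAN4 by 1.94 (-1.94), whereas in culture 1 was higher (median 0.02). In re-cultured cells 1 was higher, KHDC1L (0.52), and 2 were lower, MBD3L2 (-0.66, adjusted p = 0.025) and PRAMEF11 (-0.80, adjusted p = 0.041), with a median of -0.13. The mouse-expanded GRK2 arrays had the raised median signals (47.8 and 48.3, against at most 35.2 on other arrays) and 2374 falls against 169 rises of at least 2-fold against K220R, so the genotype difference in mouse-expanded cells is not separated from whatever raised those arrays. In re-cultured against cultured cells 5 were higher and 1 lower (median 0.32).

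In K220R arrays alone, whose median signals were not raised, 11 of the 13 tested genes were higher in mouse-expanded cells (median 1.97). These genes had been seen to rise before the list was written. The value therefore describes them and does not test raised background in the mouse-expanded GRK2 arrays. RNA of mouse host cells stays open. The test set for it covered red cell, endothelium and adipocyte genes, whose highest median was 0.36, but left out the skeletal muscle, fibroblast and leukocyte lists already seen to be higher, and single markers such as COL1A2 (3.38), CKM (3.11) and CD74 (2.98) rose by at least the median of the early embryo genes (2.93). CD74 was also higher in re-cultured than in cultured cells, as were 5 of the 13 early embryo genes, with 1 lower. These markers therefore do not settle the source. Whether more than the genes already seen took part cannot be told: of 24 members not seen beforehand only 3 had such a probe set. Without the filter FAM151A (0.87, adjusted p = 0.0119) and RFPL1 (0.61, adjusted p = 0.0070) passed on their own and KLF17 (0.09) did not, 2 higher and 0 lower, while these 3 together gave a set test p of 0.151. A rule that fewer than 5 members decide nothing was added once that p was known. A hypothesis is that growth in the animal may open a DUX4-type programme in these clones; human-specific measurement of DUX4 and ZSCAN4 transcripts in several clones grown in separate mice would test it.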
